A study of Mus musculus with 4 samples.

How the data were processed

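RNA from cultured mouse cells was measured on 4 single-channel oligonucleotide arrays, 1 for each of 4 groups. Mouse embryonic fibroblasts (MEFs) received either a control adenovirus (Ad-control) or an adenovirus carrying PGC-1α (Ad-PGC-1α) and were collected 24 h later, and brown adipocytes differentiated in culture were either wild type (WT) or lacking PGC-1α (KO). Per the labels' protocols, 300 ng of total RNA was used for each array and biotin-labelled with whole-transcript kits. The labels do not say that the adipocytes received a virus, which part of the gene was deleted, or whether the KO and WT cells came from littermates.

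The deposited values are log2 expression levels per probe set, made with RMA in Affymetrix Expression Console per the submitters' processing notes. RMA corrects background, normalizes the distributions of the arrays it is given and summarises the probes of each probe set. Versions and the genome build are not given in the sources used here. The medians over all 35556 probe sets were 6.58 (MEF Ad-control), 6.61 (MEF Ad-PGC-1α), 5.73 (adipocyte KO) and 5.72 (adipocyte WT), so the arrays of a pair share a distribution and the pairs look separately normalized. Levels were therefore compared only within a pair. RMA forces the arrays of a pair to nearly the same distribution, so a change of total RNA per cell would not be visible, and log2 differences are compressed for probe sets close to background or close to the top of the scale.

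Probe sets were named from the platform annotation. One gene symbol was given for 21789 probe sets, several for 1621 and none for 12146, and gene counts used those with 1 symbol, which made 19938 genes. The 999 genes with several probe sets were represented by the one with the highest mean over the 4 arrays. A gene was called expressed in a comparison when its level reached the median of the named genes on at least 1 of the 2 arrays compared. No genome coordinates were used.

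Each comparison was the difference of log2 levels per gene, Ad-PGC-1α minus Ad-control in fibroblasts and KO minus WT in adipocytes. With 1 array per group there is no spread between replicates, and no test, p-value or error is given between groups. Genes were counted by a rule of size, at least 2-fold higher or lower. The number of arrays limits the precision of every value, and every difference mixes the effect of PGC-1α with whatever else differed between the 2 cultures.

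Lists of genes (39, and 2 unions, of the 7 secreted and matrix lists and of the 5 mitochondrial lists) were fixed before the data were examined, as were the rules, the choice of named genes and the alternatives. For each list the median difference of its expressed members was set against 10000 random lists of the same size, drawn from expressed genes in 20 bins of mean level, and a list is said to stand apart when its median lay below the 2.5th or above the 97.5th percentile. This describes these arrays. The genes of a list are regulated together and are not independent, so the percentile is not a p-value. Of 1384 listed names, 1263 matched a named gene, 7 of them through a synonym, and 121 did not and were not analysed here. A few synonyms at first led to wrong genes. The matching was corrected after the data had been examined, and all list results come from the corrected matching.

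Named genes were chosen by rule: the PGC-1 family, the 10 largest increases and decreases of each comparison (leaving out predicted genes, olfactory and vomeronasal receptors, small RNAs and pseudogenes), up to 3 members of each list in each direction, up to 10 genes per combination of directions past 2-fold in both comparisons, and 4 adipocyte markers. Members of a gene family with similar sequence, such as Ly6g, the Ifit genes and the Oas genes, can share hybridisation and are uncertain as single genes.

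The counting was tested on simulated data with normally distributed noise. Its SD came from the median absolute deviation of the differences of expressed genes, 0.510 in fibroblasts and 0.279 in adipocytes. The plain SDs were larger, 0.681 and 0.422, so the tails of the differences were not simulated. Of 50 genes changed 2-fold, 64% passed the rule in the fibroblast comparison and 54% in the adipocyte comparison, and all 50 changed 4-fold passed in each. Of unchanged genes, 5.41% (549 of 10155) passed in the fibroblast simulation and 0.0399% (4 of 10036) in the adipocyte simulation. The real spread holds biology as well as noise, and without replicates the noise itself is unknown, so these shares are not upper limits. Of 100 simulated lists of 30 unshifted genes, 3 stood apart in each comparison, against 99 (fibroblasts) and 100 (adipocytes) of 100 lists shifted by 0.5 log2 units.

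The alternatives were no filter on levels, a filter at the 75th percentile, subtraction of a loess fit of the difference on the level or of the median difference, the mean of all probe sets of a gene, size rules of 1.5-fold and 3-fold, counts over all probe sets, and the mean of list members in place of the median. Calculations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.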

Results

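Gene expression was measured on 4 arrays, 1 per group, in mouse embryonic fibroblasts given a control or a PGC-1α adenovirus and in differentiated brown adipocytes with or without PGC-1α. PGC-1α, encoded by Ppargc1a, is a transcriptional coactivator of mitochondrial and oxidative metabolism genes. The series title names secreted protein genes and the secretome as its subject, so the fibroblast pair asks which genes differ when PGC-1α is added and the adipocyte pair asks which differ when it is missing. No group had a replicate, so no difference below has an error or a test, and "higher" and "lower" describe the arrays compared.

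Ppargc1a was the gene with the largest difference in fibroblasts. Its level was 6.48 log2 units with Ad-control and 13.51 with Ad-PGC-1α, a difference of 7.03 log2 units or 131-fold. In adipocytes it was 8.09 in WT and 7.54 in KO, a difference of -0.55 (1.47-fold lower). Ppargc1a has another, dimmer probe set, which differed by -0.07 in fibroblasts and -0.31 in adipocytes. The adipocyte values do not settle whether the KO array matches its label, because the labels do not give the deleted part and a probe set outside it checks nothing. The relative Ppargc1b was 7.27 with Ad-control and 6.74 with Ad-PGC-1α, and 9.52 in WT and 9.12 in KO. Pprc1, the remaining family member, differed by -0.54 in fibroblasts and -0.04 in adipocytes.

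In fibroblasts, genes of mitochondrial oxidation were higher with Ad-PGC-1α as a group. Of 199 expressed genes in the mitochondrial lists, 81 were at least 2-fold higher, 0 were 2-fold lower and 118 passed neither size, and their median difference was 0.89 log2 units, against -0.09 to 0.02 for the middle 95% of matched random lists. Of 76 nuclear-encoded genes of oxidative phosphorylation, 36 were at least 2-fold higher and 0 lower (median 0.97). They included the cytochrome oxidase subunit Cox7a1 (7.11 with Ad-control, 12.81 with Ad-PGC-1α), the complex III subunit Uqcrfs1 (difference 1.97) and the complex I subunit Ndufb10 (1.85). In the tricarboxylic acid cycle 15 of 23 genes were 2-fold higher and 0 lower (median 1.07), with Idh3a 3.11-fold, Sdhd 3.09-fold and Sucla2 2.86-fold higher, while Pcx, the pyruvate carboxylase, differed by -0.60. Fatty acid oxidation and transport had 16 of 35 genes 2-fold higher and 0 lower (median 0.89), led by Pdk4, which restrains pyruvate dehydrogenase, 21.0-fold higher, Acadvl, the very long chain acyl-CoA dehydrogenase, 5.40-fold higher and Hadhb 4.09-fold higher. Genes of mitochondrial gene expression, import and dynamics had 17 of 61 genes 2-fold higher and 0 lower (median 0.69), among them Gfm1, Timm10 and Mfn1 at 1.81, 1.72 and 1.69 log2 units.

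Nuclear receptors and coregulators of oxidative metabolism had a median of 0.25, with 5 of 29 genes 2-fold higher and 0 lower. Esrra, the receptor ERRα, was 5.06-fold higher, the deacetylase Sirt3 4.11-fold and Ppara 3.84-fold. That list no longer stood apart when only genes above the 75th percentile of level were used (0.22). Brown adipocyte thermogenic genes stood apart with a median of 1.64, and 8 of 14 were 2-fold higher and 0 lower. Cox7a1 and Pdk4 led them, followed by the growth factor Bmp8b at 2.25, and Lhx8 and Zic1 had differences of -0.82 and -0.81. Ucp1 itself lay low on both arrays, at 5.51 and 5.08. Antioxidant genes grouped with the mitochondrial lists (median 0.12) and the 2 mitochondrially encoded genes measured (0.19) lay inside the random range. For the antioxidant list that range was wide, -0.30 to 0.31. Of the 8 antioxidant genes expressed, 5 were higher, led by Prdx3 (1.20), Sod2 (0.81) and Txn2 (0.62). The other 3 were lower, Cat (-0.47), Glrx2 (-0.20) and Sod1 (-0.07).

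Secreted and matrix genes were lower with Ad-PGC-1α in fibroblasts as a group. Of 288 expressed genes in the 7 lists, 48 were at least 2-fold lower, 17 were 2-fold higher and 223 passed neither size, and the median was -0.38, against -0.10 to 0.01 for random lists. With no filter on level the median was -0.19. The lists do not hold every secreted gene, and Apela, a secreted peptide hormone 24.2-fold higher, is in none of the 7. Matrix glycoproteins and matricellular proteins had 15 of 58 genes 2-fold lower and 0 higher (median -0.52), with Ccn5 3.85-fold, Mfap2 3.15-fold and Mfap5 3.02-fold lower. Collagens had a median of -0.46, and 20 of 21 differences were negative although 1 gene, Col3a1, was past 2-fold (2.67-fold lower). Secreted matrix enzymes and protease inhibitors had a median of -0.42, with 8 of 54 genes 2-fold lower, such as the plasminogen activator Plat (-1.75) and the aggrecanase Adamts5 (-1.57), and 2 higher, Plau (1.08) and Mmp8 (1.03). Complement and other plasma proteins had a median of -0.52, with 4 of 33 genes 2-fold lower and 1 higher. Proteoglycans had a median of -0.20, inside the random range, with Ogn 3.10-fold, Aspn 2.45-fold and Podn 2.34-fold lower.

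Growth factors and their secreted modulators differed in both directions. Of 78 genes, 16 were 2-fold lower and 5 higher, with a median of -0.43. Angptl7 was 10.5-fold lower, the lymphatic growth factor Vegfd 3.07-fold and Angpt1 2.95-fold lower, while Pdgfb was 5.67-fold, Bmp8b 4.75-fold and Fgf9 3.43-fold higher. Chemokines and cytokines had 9 of 36 genes 2-fold higher and 1 lower. Cxcl11, Cxcl3 and Cxcl2 were higher by 3.96, 2.32 and 2.19 log2 units, and Cxcl14 was 2.68-fold lower. The median of this list, 0.14, stood apart with the filter at the median level, but was 0 with no filter and -0.01 with the filter at the 75th percentile, so the list as a whole has no firm direction.

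Genes of the cell cycle and DNA replication were lower with Ad-PGC-1α, with a median of -0.74 and 48 of 52 differences negative, 5 of them past 2-fold and none past 2-fold higher. E2f8 was 2.82-fold lower, Uhrf1 2.39-fold and Ccnd1, cyclin D1, 2.30-fold. Cholesterol synthesis and uptake genes had a median of -0.61 with 17 of 18 negative, and Fdft1, squalene synthase, was 2.57-fold lower. Fibroblast and contractile genes had 26 of 26 negative differences (median -0.53), with Snai2 2.57-fold and Pdgfrb 2.16-fold lower. Adipocyte precursor genes had a median of -0.56, with Gas1 3.58-fold and Zfp521 3.30-fold lower and Gata3 3.32-fold higher, but their median moved inside the random range with no filter (-0.24). Targets of p53 had a median of -0.31 and 0 of 22 past 2-fold, and lost their place apart under the stricter filter (-0.22).

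The lists for other processes lay inside the random range in fibroblasts with the planned main settings. Interferon-stimulated genes had a median of -0.04, with 1 of 47, Irf1, past 2-fold (2.12-fold lower). Medians were -0.14 for the NF-kB response, 0.06 for immediate early genes, -0.09 for heat shock factor targets, -0.10 for the unfolded protein response, -0.09 for protein export machinery, -0.04 for cytosolic ribosomal proteins and -0.03 for housekeeping genes. Glycolysis and lactate genes had a median of 0.11 with 4 of 21 genes 2-fold higher, among them Ldhb, a lactate dehydrogenase subunit, 10.5-fold, and stood apart with all probe sets averaged (0.21) and under the stricter filter (0.22). Medians were -0.26 for fatty acid synthesis, 0.22 for creatine, glycogen and muscle-type energy genes, -0.08 for general adipocyte genes and -0.18 for white adipocyte-enriched genes. Under the stricter filter fatty acid synthesis (-0.45), creatine, glycogen and muscle-type energy genes (0.98) and white adipocyte-enriched genes (-0.50) stood apart. Of other cell types, markers had medians of -0.14 (skeletal muscle), -0.07 (leukocytes), -0.43 (endothelium), 0.16 (epithelium) and -0.31 (neural crest and glia). Sex-linked genes had a median of -0.29, which pools Xist with Y-linked genes and so does not bear on a difference of sex.

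Over all genes, 670 of 10414 expressed genes were at least 2-fold higher with Ad-PGC-1α and 500 were at least 2-fold lower. After a loess fit of the difference on level was subtracted the split was 775 higher and 360 lower, which moves the share of higher genes from 57.3% to 68.3%. At 1.5-fold the balance turned, with 1421 higher and 1699 lower. Behind Ppargc1a, the largest increases were Cox7a1 (52.0-fold), Ly6g (34.3-fold), Cend1 (29.3-fold), Zdhhc23 (27.5-fold), Apela, a secreted peptide hormone (24.2-fold), Fmo2 (22.0-fold), Cdk15 (21.5-fold), Pdk4 (21.0-fold) and Elovl7 (20.6-fold). Apart from Pdk4, these genes lay below the median of named genes (7.67) on the Ad-control array. Their fold sizes and order are therefore uncertain. The decreases were smaller. Angptl7 was 10.5-fold lower and Lrrc17 7.75-fold lower, and Mrgprf, Cpxm1, Gpr153, Chl1, Tspan11, Ptgir, Nrep and Igsf10 were between 5.05-fold and 4.50-fold lower.

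**Figure D1:**
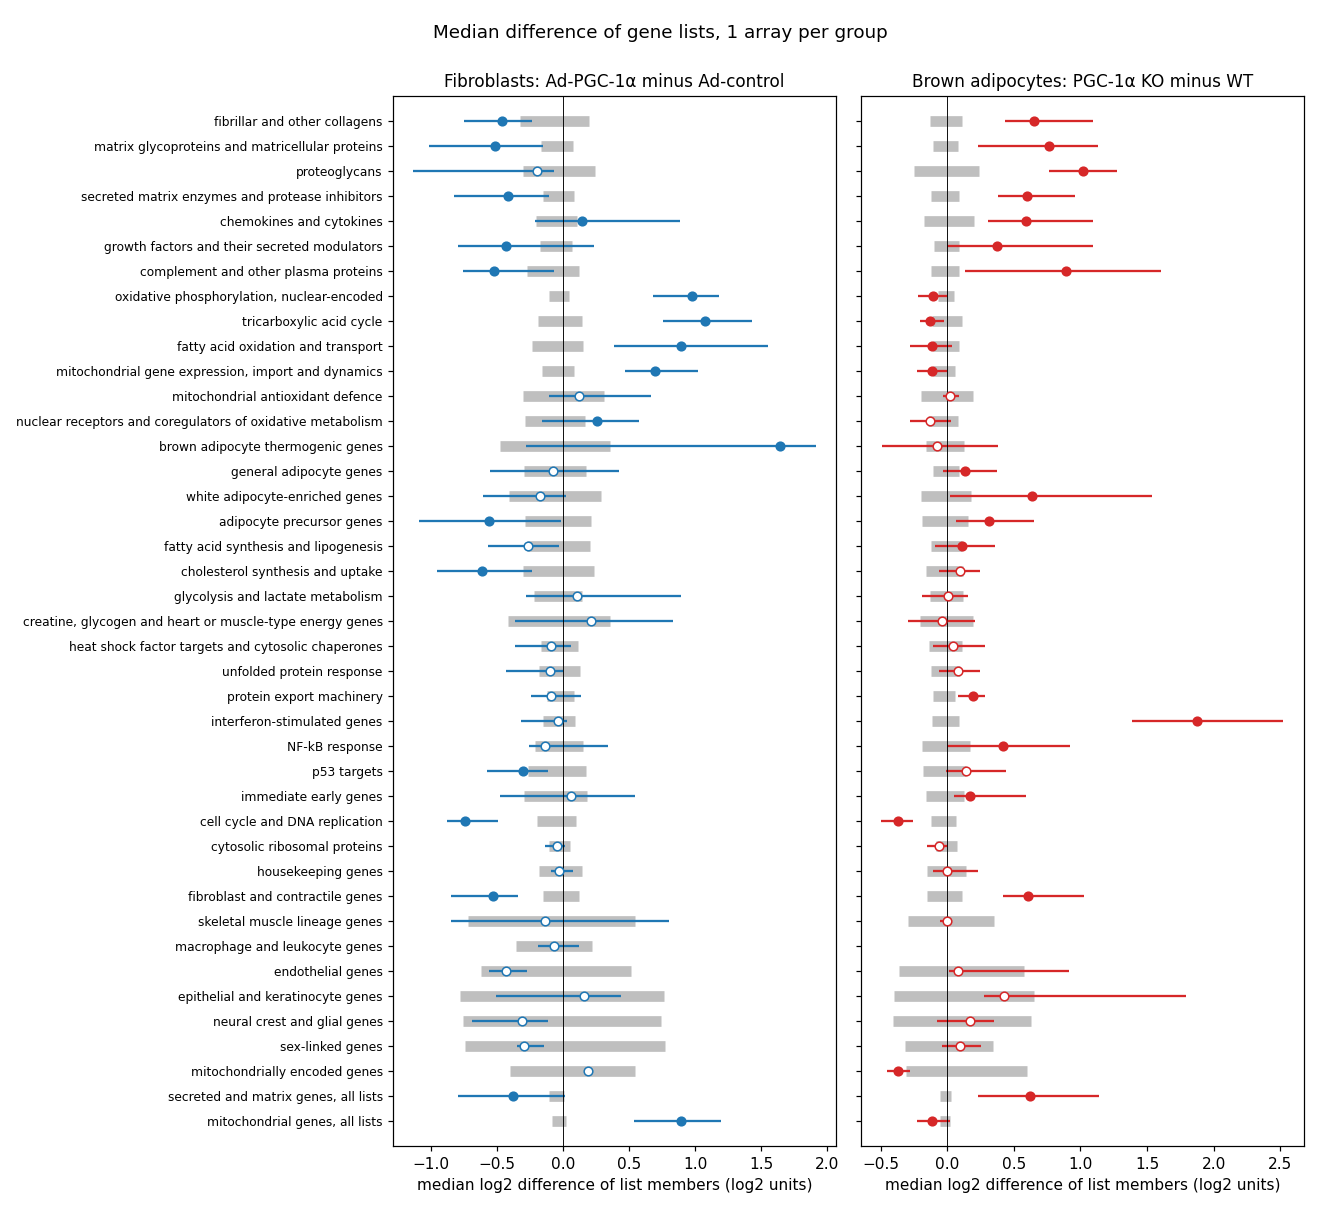
Median log2 difference of the expressed members of each gene list in fibroblasts (Ad-PGC-1α minus Ad-control, left) and brown adipocytes (KO minus WT, right), with the interquartile range of members as a line, the middle 95% of matched random lists as a grey bar, and filled points for lists that stand apart. The mitochondrial union lies at 0.89 in fibroblasts and -0.11 in adipocytes, and the secreted and matrix union at -0.38 and 0.62.

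In brown adipocytes, secreted and matrix genes were higher in KO than in WT. Of 226 expressed genes in the 7 lists, 71 were at least 2-fold higher, 2 were 2-fold lower and 153 passed neither size, and the median was 0.62, against -0.06 to 0.03 for random lists. With no filter on level the median was 0.30. All 7 lists stood apart. Proteoglycans had a median of 1.02 with 6 of 9 genes 2-fold higher, and the largest, Dcn (decorin), was 5.40-fold higher, at 7.76 in WT and 10.20 in KO. Complement and other plasma proteins had a median of 0.89, with 14 of 35 genes 2-fold higher and 1 lower, from Trf, transferrin, 10.0-fold, Itih4 7.61-fold and Apod 7.36-fold higher to the glutathione peroxidase Gpx3, 3.23-fold lower. Matrix glycoproteins had a median of 0.77, with 16 of 50 genes 2-fold higher and 1 lower. Thbs2 was 4.28-fold, Tnc 3.22-fold and Efemp1 3.16-fold higher, and the laminin chain Lama5 2.45-fold lower.

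Collagens had a median of 0.65 with 8 of 26 genes 2-fold higher and 0 lower, including Col8a1 (4.19-fold), Col28a1 (2.62-fold) and Col6a3 (2.40-fold). Secreted matrix enzymes and protease inhibitors had a median of 0.60 with 9 of 41 genes 2-fold higher and 0 lower. The gelatinase Mmp2 was 4.32-fold, the metalloproteinase inhibitor Timp1 3.77-fold and Serpina3n 3.40-fold higher. Growth factors and their modulators had a median of 0.38 with 15 of 54 genes 2-fold higher and 0 lower, among them Angpt2, Fgf10 and Gas6 at 1.72, 1.71 and 1.65 log2 units, while Igf2 differed by -0.96. Chemokines and cytokines had a median of 0.59 with 14 of 14 differences positive and 4 past 2-fold, Cxcl10 (7.20-fold) and Cxcl13 (5.14-fold) being the largest. Under the filter at the 75th percentile its median was larger, 1.14, but lay at percentile 97.2 of random lists and did not stand apart. Protein export machinery had a median of 0.19, and 46 of 54 differences were positive with 0 past 2-fold.

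Interferon-stimulated genes were the list with the largest median in KO adipocytes. The median was 1.87 log2 units, 43 of 43 differences were positive and 39 were past 2-fold. Ifit3 was 5.54 in WT and 9.78 in KO (19.0-fold higher), Ifit1 was 13.0-fold higher, and Rtp4, Oasl2, Rsad2 and Iigp1 were between 9.76-fold and 8.83-fold higher. The NF-kB response had a median of 0.42, with 4 of 15 genes 2-fold higher, including the acute phase genes Lcn2 (5.87-fold) and Saa3 (2.79-fold). None of the 22 leukocyte genes on the array reached the level of expression in either adipocyte array. Immediate early genes had a median of 0.17, which stood apart except under the stricter filter (0.15).

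Mitochondrial genes differed little between KO and WT. Their median was -0.11, below the random range of -0.05 to 0.02, with 0 of 205 past 2-fold in either direction. Oxidative phosphorylation (-0.11), the tricarboxylic acid cycle (-0.13), fatty acid oxidation (-0.11) and mitochondrial gene expression (-0.11) each stood apart as slightly lower, though fatty acid oxidation did not after loess or with no filter. The median was 0.02 for antioxidant genes and -0.13 for nuclear receptors, both inside the random range. Within these lists Ppara was 2.27-fold lower in KO, and Pdk4 (1.96-fold) and Ndufs5 (1.92-fold) came next. The 2 mitochondrially encoded genes measured had a median of -0.37, which stood apart except when all probe sets of a gene were averaged.

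Adipocyte genes were present in both genotypes. Adipoq was 11.20 in WT and 11.45 in KO, Fabp4 12.47 and 12.44, Pparg 11.73 and 11.59, and Ucp1 8.51 and 8.66. General adipocyte genes had a median of 0.13, above the random range, with 2 of 39 genes 2-fold higher, Npr3 (2.33-fold) and Pck1 (2.08-fold). White adipocyte-enriched genes had a median of 0.64 with 3 of 11 genes 2-fold higher, Agt (4.75-fold), Hoxc8 (4.52-fold) and Dpt (4.29-fold), and did not stand apart under the stricter filter (0.18). Thermogenic genes had a median of -0.07, inside the random range, with Lhx8, a homeobox gene, 10.3-fold, Fgf21 2.32-fold and Zic1 2.15-fold higher and Ppara lower, but stood apart as lower (-0.30) under the stricter filter. Precursor genes had a median of 0.31, with F3 3.48-fold and Pdgfra 2.06-fold higher. Fibroblast and contractile genes had a median of 0.60, with 8 of 23 genes 2-fold higher and 0 lower, including Acta2, smooth muscle actin (2.66-fold), Twist2 (2.42-fold) and Col1a2 (2.26-fold). Fibroblast markers and secreted and matrix genes were therefore higher in the same sample, though some genes, such as Col1a2, are in both kinds of list. The 29 fibroblast and precursor genes outside the secreted lists had a median of 0.44.

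Cell cycle genes were lower in KO, with a median of -0.37 and 48 of 51 differences negative. Of these, Mki67 was past 2-fold (2.01-fold lower). Fatty acid synthesis genes had a median of 0.11, just above the random range, and did not stand apart with no filter, after loess or with all probe sets averaged. Medians inside the random range were 0.10 for cholesterol synthesis, 0.01 for glycolysis, -0.04 for creatine, glycogen and muscle-type energy genes, 0.04 for heat shock factor targets, 0.08 for the unfolded protein response, 0.14 for p53 targets, -0.06 for ribosomal proteins and -0.002 for housekeeping genes. The p53 targets stood apart with no filter (0.22) and with all probe sets averaged (0.18). Markers of skeletal muscle (-0.0015), endothelium (0.08), epithelium (0.43) and neural crest and glia (0.17) also lay inside it, on 3 to 5 expressed genes each. The sex-linked genes (0.10, on 4 expressed genes), which mark no cell type, did so as well. Epithelial genes stood apart under the stricter filter (3.16), which is the value of Krt19 alone.

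Over all genes, 294 of 10277 expressed genes were at least 2-fold higher in KO and 46 were at least 2-fold lower. Over all probe sets, named or not, the counts were 365 and 105. Of the 294, 71 (24.1%) were in the secreted and matrix lists, which hold 2.20% of expressed genes, and 39 (13.3%) were in the interferon-stimulated list. The secreted lists are not complete, and Ahsg, named next, is in none of them. Behind Ifit3 and Ifit1 the largest increases included Ahsg, the plasma protein fetuin-A (10.4-fold), Lhx8 (10.3-fold), Trf (10.0-fold) and the keratin Krt19 (8.92-fold). The largest decreases were Tex11 (7.95-fold), the transcription factor Tbx1 (7.39-fold), the chloride channel Ano1 (4.70-fold), St3gal6 (4.67-fold), the cell cycle inhibitor Cdkn1c (3.72-fold), Eya4 (3.44-fold), Agmo (3.29-fold), Osbpl6 (3.29-fold), Prxl2b (3.26-fold) and Gpx3 (3.23-fold).

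Set against each other, the comparisons shared few large differences. Across 9158 genes expressed in both, the differences had a Pearson r of -0.12 and a Spearman rho of -0.11, genes not being independent replicates. Lower with Ad-PGC-1α and higher in KO were 41 genes, against 9.30 for independent lists. These 41 included the angiotensin receptor Agtr2 (-2.11 in fibroblasts, 1.76 in adipocytes), Tmem119 (-1.98 and 1.66), the sphingosine phosphate receptor S1pr3 (-1.50 and 1.73), Lrrc17 (-2.95 and 1.36) and Ogn (-1.63 and 1.30), and 13 of them were in the secreted and matrix lists. Kcnj15, Atp8b1, Cyp1b1, Casp12 and Olfml3 were also among them. The reverse combination held 3 genes against 1.41: Ppara (1.94 and -1.18), Plce1 (1.03 and -1.19) and Clic5 (1.24 and -1.03). Genes higher in both numbered 8 against 13.5, namely Adcyap1r1, Fmo2, Cxcl13, Edn1, Npr3, Sprr1a, Itih5 and St3gal5, and 0 were lower in both against 0.97.

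Of 192 secreted and matrix genes expressed in both comparisons, 139 were lower with Ad-PGC-1α and higher in KO and 6 were the reverse, so 75.5% had opposite signs, against 53.2% of all genes. That share is largely set by the separate shifts of the list, with 213 of 288 genes lower in fibroblasts and 194 of 226 higher in KO. The value of all genes is therefore no baseline for it. Within this list the size of one difference did not track the other, with a Pearson r of 0.05 and a rho of 0.01 across its genes. Of 198 mitochondrial genes, 133 were higher with Ad-PGC-1α and lower in KO and 8 were the reverse, with an r of -0.32 and a rho of -0.18 across genes. These counts too are largely set by the separate shifts, with 183 of 199 genes higher in fibroblasts and 147 of 205 lower in KO.

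**Figure D2:**
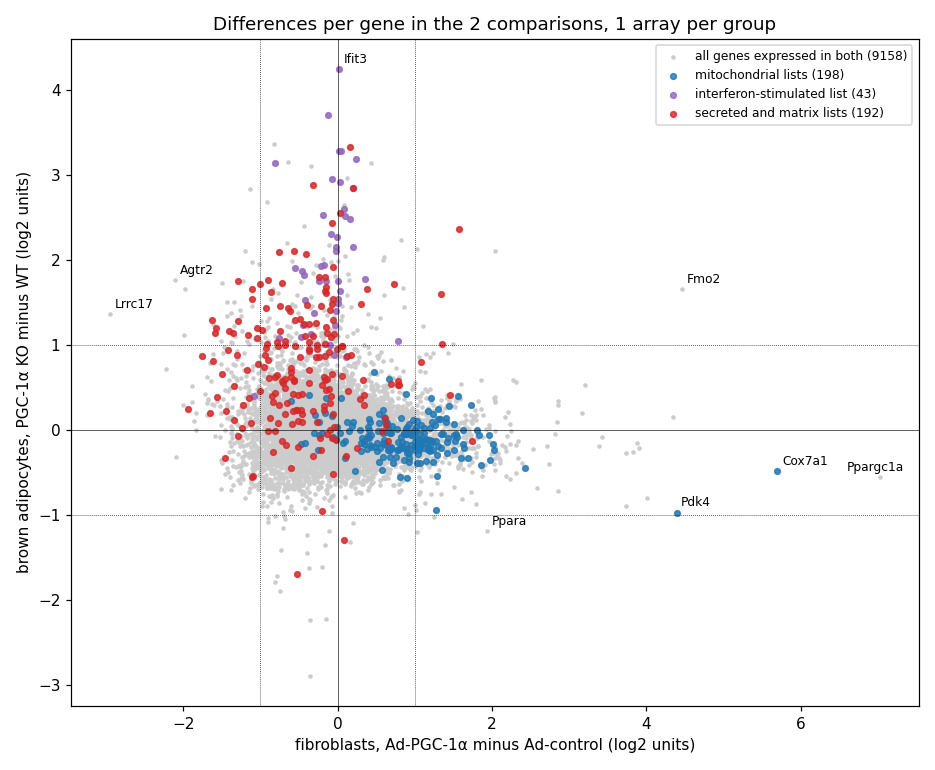
Each point is 1 of 9158 genes expressed in both comparisons, with the fibroblast difference (log2 units, Ad-PGC-1α minus Ad-control) on the x axis and the adipocyte difference (log2 units, KO minus WT) on the y axis, dotted lines at 2-fold and colours for the mitochondrial (198), interferon-stimulated (43) and secreted and matrix (192) genes. The secreted and matrix genes gather at the upper left, where 139 of 192 lie, and the interferon-stimulated genes spread upward near 0 on the x axis.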

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

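The medians after loess come from an alternative planned before the data were examined. Their use beside an explanation, like the tests in this part, was chosen after the results had been seen. An earlier test of fewer dividing fibroblasts, whose outcome could not have counted against that explanation, was replaced by the test on fibroblast genes after the values were known, and the bounds of several other tests were changed at the same time.

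The lists for chemokines and for the cell cycle stood apart in the same direction in both comparisons, although the comparisons change PGC-1α in opposite ways. Taking more minus less PGC-1α, the chemokine median was 0.14 in fibroblasts and -0.59 in adipocytes, a difference of 0.73, and the cell cycle median was -0.74 and 0.37, a difference of -1.11. The difference between cell types was not tested, since each rests on 1 array per group, and the fibroblast chemokine median was 0 with no filter on level.

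Probe sets outside the named genes also carried differences. Among expressed probe sets with several symbols, 34 were at least 2-fold higher and 4 lower with Ad-PGC-1α, and 25 were higher and 0 lower in KO. Among those with no symbol, 90 were higher and 36 lower with Ad-PGC-1α. In KO 37 of these were higher and 59 lower, with a largest decrease of -3.37, whereas of the named genes 294 were higher and 46 lower.

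Secreted and matrix genes were lower with Ad-PGC-1α and higher in KO adipocytes. A trend of the difference with level would be shared by the random lists, which were drawn in 20 bins of mean level. After loess the medians were 0.65 in adipocytes and -0.31 in fibroblasts, both still outside the random range. Because of that matching, loess is no separate test of such a trend. Members of the interferon, NF-kB and chemokine lists are not what sets the adipocyte median, which was 0.63 over the 209 genes left without them. They were few among the 226 genes, so this outcome was nearly fixed beforehand. Inflammation acting on other secreted genes was not tested. In fibroblasts, the fibroblast and precursor genes outside the secreted lists had a median of -0.52, so the lower values may belong to a shift of fibroblast genes as a whole rather than of secreted genes. More undifferentiated fibroblast-like cells in the KO culture stay open, because the same genes were higher there (0.44) while general adipocyte genes were not lower (0.13). An effect of PGC-1α on these genes is the biological hypothesis the design names, and with 1 culture per genotype it cannot be separated from a difference between cultures.

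Interferon-stimulated genes were higher in KO adipocytes. Leukocyte RNA in the KO sample is argued against, since the 22 leukocyte genes had a median difference of -0.015 and 0 were expressed. The median after loess was 1.88, which is no separate test of a trend with level, since the random lists were already matched for level. An effect of the genotype and an interferon response in 1 culture stay open, since 1 culture per genotype was measured. In the fibroblast pair, where both cultures had received virus, the list had a median difference of -0.04. Some of its genes were high on both arrays, such as Ifit3 (12.85 with Ad-control, 12.87 with Ad-PGC-1α) and Oasl2 (13.20 and 13.21). Fibroblasts without virus were not measured, so a response shared by both cultures would not show in this difference.

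Chemokines such as Cxcl11, Cxcl3 and Cxcl2 were higher with Ad-PGC-1α. The interferon-stimulated list showed no rise as a set, with a median of -0.040, inside the random range. It had 18 members above 0 and 29 below, and 0 of 47 were 2-fold higher. A stronger interferon response to the virus is therefore not shown. It is not excluded either, because some of these genes were high on both arrays, where differences are compressed, and each group had 1 array. The 15 NF-kB genes outside the chemokine list had a median of -0.21, with 6 above 0 and 9 below. A general NF-kB response is thus not shown, but stays open, since the random range for so few genes was wide, -0.30 to 0.22. Neither response can be told apart from an effect of PGC-1α. Viral dose and its equality between the cultures are not given in the sources used here.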

How the results depend on the processing

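The settings here were planned, and counting the lists that stand apart under each was added after the results had been seen. The 43 list results that stood apart, 19 in fibroblasts and 24 in adipocytes, gave 258 alternative medians, of which 256 kept their direction. The 2 exceptions were fibroblast chemokines, at -0.00824 with the filter at the 75th percentile and 0 with no filter; the cause was not tested. The lists standing apart numbered 17 to 20 in fibroblasts and 22 to 24 in adipocytes. Named genes past 2-fold gave 196 results, a gene past it in both comparisons counting in each. These results kept their direction in 588 of 588 values and stayed past 2-fold in 579. The genes were chosen largely for the size of their differences. Loess, subtraction of the median and the mean of probe sets, the alternatives used for genes, move most of them little. Their kept direction was therefore nearly fixed beforehand. With the stricter filter, which leaves fewer genes, counts were 366 higher and 211 lower with Ad-PGC-1α, 153 and 17 in KO, 13 lower with Ad-PGC-1α and higher in KO, and 0 the reverse. In the same order they were 1421, 1699, 646, 285, 188 and 31 at 1.5-fold and 248, 61, 112, 12, 2 and 0 at 3-fold. The sizes follow from the rule, but at 1.5-fold the fibroblast balance turned to more lower than higher genes. The fibroblast differences of expressed genes had a median of -0.056 and quartiles of -0.41 and 0.28, with more large increases than large decreases. Why they were distributed in this way was not tested. Over all probe sets 105 were 2-fold lower in KO, beside 365 higher. Ppargc1a differed by 3.48 in fibroblasts when both probe sets were averaged, since the dimmer one did not differ. The correlation was -0.093 with no filter and -0.17 with the stricter one. The secreted median in adipocytes was 0.71 as a mean, 0.30 with no filter, 0.85 with the stricter filter and 0.65 after loess, and in fibroblasts -0.30 as a mean, -0.19 with no filter, -0.31 after loess and -0.32 with the median subtracted. The mitochondrial median in fibroblasts was 0.94 after loess and 0.95 with the median subtracted, and in adipocytes -0.0911 and -0.0906. Where no cause is given, it was not tested. In place of a spread between replicates, list medians were judged against 1 SD of random lists and the correlation against its spread over genes, 0.0103, which is too small where genes are not independent. No paired analysis was possible because each group has 1 array. Genes near background are not resolved, and those near the top of the scale are compressed.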

Other observations

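Levels of several named genes are given here for the adipocyte arrays. The homeobox gene Lhx8 was 6.83 in WT and 10.20 in KO, Zic1 was 2.15-fold higher in KO and Hoxc8 4.52-fold higher, while Tbx1 was 9.93 in WT and 7.04 in KO and Eya4 was 3.44-fold lower in KO. The keratin Krt19 was 5.99 in WT and 9.15 in KO. These genes were set side by side after their values were seen, they form no list fixed beforehand, and no explanation of them was tested.

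In fibroblasts, where Ppargc1a differed by 7.03 log2 units, 1170 genes passed 2-fold. In adipocytes, where its measured difference was -0.55, 340 genes passed, and 86.5% of them were higher in KO. Counted over all probe sets, 365 were higher and 105 lower.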
